A study of Mus musculus with 6 samples.

How the data were processed

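RNA was measured in Lin-Thy1.2+ innate lymphoid cells (ILCs) sorted from the lungs of C57BL/6J mice, 3 samples from wild-type mice (WT) and 3 from Rbm3 knockout mice (RBM3KO). ILCs are lymphocytes without rearranged antigen receptors, and the Lin- gate is set to leave out cells that carry markers of other blood lineages. Which lineage antibodies were used is not given in the sources used here. Per the labels, all mice were challenged with the fungal allergen Alternaria alternata, at 25 µg given 3 times over 7 days. Per the labels' protocols, RNA was extracted with a miRNeasy kit, polyA RNA was turned into cDNA by the Smart-seq2 protocol, and libraries were made with the Nextera XT kit. Smart-seq2 with Nextera XT does not mark strand and carries no molecular identifiers in its standard form, so reads from overlapping genes on opposite strands cannot be told apart and PCR copies are counted.

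The authors deposited 1 table of raw read counts per gene symbol, with 1 column per sample and no pooling. The unit is counts, as the whole numbers and the different column totals show. The submitters' processing notes name Bowtie 1.0.0, STAR 2.6.1c, featureCounts 1.6.5 and the mouse genome build mm10, with no role or order. The gene annotation, the strand setting and any filter on reads are not given in the sources used here. The table holds 14416 genes, of which 0 have a total of 0, and 0 columns of other samples. Reads that map to near-identical genes, such as histone and tubulin copies, can be split or lost in such counting, so single values of those genes are uncertain. The table starts from reads already assigned to genes, so mapping rates and the coverage of single exons were not examined.

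The total count was 13339633, 16747682 and 25068137 in WT replicates 1, 2 and 3 and 15843924, 16936670 and 7498247 in RBM3KO replicates 1, 2 and 3. The deepest library held 3.34 times the counts of the shallowest. A count of 0 allows up to 3 counts, which is between 0.120 and 0.400 CPM in these libraries. CPM is a count relative to the total of its library, as edgeR's cpm scales it. Such floors cover counting error only. No 2 libraries held identical values, and the lowest chi-square per degree of freedom over genes between any pair was 22.3, so all 6 were kept as separate samples. Spearman's rho over genes, which are not independent replicates, lay between 0.942 and 0.968 for the pairs of libraries. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

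Genes were filtered with edgeR's filterByExpr by genotype, which left 11382 genes holding 99.9% of the counts, and scaled by TMM. WT and RBM3KO were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit, no covariate), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are RBM3KO minus WT. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Levels are TMM-normalised CPM, given as mean ± SD over 3 libraries, except that summed levels of a list are CPM of the total count, without TMM. A design of 3 against 3 cannot give an exact permutation p under 0.1 for a single value, so the tests rest on the model fitted across all genes. Rbm3 was left out of the counts of changed genes.

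The 24 gene lists, the tests, the samples and the rule for named genes were chosen before the data were examined. Lists were tested with limma's camera (limma 3.58.1, preset correlation 0.01, two-sided) on voom log2 CPM, adjusted over the lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move one way and does not compare the list with other genes. Markers of T cells, B cells, myeloid cells, granulocytes and mast cells, epithelium, stroma and endothelium, and erythroid cells and platelets served as checks for carried-over cells. The rule for named genes takes Rbm3, up to 12 genes per direction with the largest log2 fold change among those past the threshold at a mean of at least 10 CPM with no overlap between the genotypes, 18 fixed ILC genes, and from each list up to 4 members past the threshold or, where there were none, the 2 with the highest mean. A direction with fewer than 5 qualifying genes was to be filled to 5, which was not needed. Predicted genes and pseudogenes were counted but not named, and not every gene that the rule takes is printed. Genes outside this rule are said to have been chosen after their values were seen.

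Gene symbols were matched to GENCODE release M21, which uses the same mouse assembly as mm10. Of the table's genes, 13007 matched by symbol, 1196 by an older symbol and 213 did not match, so 98.5% had coordinates. Coordinates are 1-based. GC content, transcript length and the 3' untranslated region came from the basic transcript with the longest coding sequence.

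The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, RLE and upper-quartile scaling, no filter on low counts, at least 10 CPM in 3 libraries, a non-robust fit, a test against a minimum fold change of 1.5, the replicate number as a block, and leaving out each of the 6 libraries in turn. A correction for transcript GC content, a correction for GC content and length, and thinning of all libraries to the depth of the shallowest were added after seeing the data. The GC correction took, for each library, a loess curve (span 0.5) of log2 CPM relative to the mean of the 6 libraries as an offset.

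The main test was tested on simulated counts with the means, library sizes and dispersions of these libraries and 200 changed genes. For RBM3KO against WT it recovered 5% of them at 1.5-fold among 10968 tested genes, 36% at 2-fold among 11018 and 61.5% at 4-fold among 10983. Beside these 10, 72 and 123 recovered genes it made 2, 9 and 9 false calls. At each fold that is a larger share of the calls than the threshold on adjusted p aims at. The calls in the real libraries may thus also hold more false ones than the threshold implies. Among changed genes at 10 CPM or more the main test recovered 8.1%, 51.5% and 91.7%. Of 24 simulated lists with no change camera called 0, in counts drawn without correlation between genes.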

Results

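Gene expression was measured by Smart-seq2 RNA-seq in lung Lin-Thy1.2+ ILCs sorted after Alternaria challenge, in 3 samples from WT and 3 samples from RBM3KO mice. Alternaria alternata is a mould whose extract evokes type 2 lung inflammation. RBM3 is a cold-inducible RNA-binding protein. The series title puts the question as whether RBM3 restrains ILCs and lung inflammation, and the comparison of the genotypes addresses the first part at the level of transcripts. The total count of a library ran from 7498247 in RBM3KO replicate 3 to 25068137 in WT replicate 3. Between 11782 and 12654 genes had at least 1 count in a library.

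Rbm3 (chromosome X, start 8138975, mm10) stood at 292 ± 22 CPM (SD, n = 3) in WT and 26.8 ± 4.63 CPM (SD, n = 3) in RBM3KO. The log2 fold change was -3.45 (SE 0.15, edgeR adjusted p = 2.2e-06). Its raw counts were 3649, 5336 and 7473 in the WT libraries and 406, 375 and 235 in the RBM3KO libraries, so every library matched its label. The knockout libraries thus still held reads assigned to Rbm3, and which part of the gene they cover was not examined. Cirbp, the other cold-inducible RNA-binding protein of this family, stood at 69.8 ± 13.2 CPM in WT and 91.1 ± 5.97 CPM in RBM3KO, which did not pass the test (log2 fold change 0.38, SE 0.17, edgeR adjusted p = 0.383).

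Beyond Rbm3, 141 of 11382 tested genes changed between the genotypes, of which 28 were higher and 113 lower in RBM3KO (edgeR, adjusted p under 0.05). Among the genes that rose were Gpr97, an adhesion G protein-coupled receptor, at 30.3 ± 7.15 against 9.96 ± 2.98 CPM (log2 fold change 1.604, SE 0.33), Nr1d2, a nuclear receptor of the circadian clock (1.32, SE 0.27), and Anxa1, the phospholipid-binding annexin A1 (1.27, SE 0.16). Il10, which encodes an anti-inflammatory cytokine, rose from 149 ± 17.2 to 283 ± 79.3 CPM (0.93, SE 0.19), and Ctla4, an inhibitory receptor of lymphocytes, from 546 ± 4.73 to 889 ± 191 CPM (0.70, SE 0.14). Ostf1, Dgkd, Sgms1, Serinc3, the protease gene Furin, Wls and Frmd4b rose with log2 fold changes between 0.65 and 0.79. Among the genes that fell, the largest log2 fold change at a mean of 10 CPM or more was that of Cebpb, a transcription factor of the C/EBP family, at 66.9 ± 44.2 CPM in WT and 3.72 ± 4.60 CPM in RBM3KO (log2 fold change -4.33, SE 0.84). Fam108c (-3.42, SE 0.46) and Cdk2ap1 (-2.83, SE 0.42) were also lower. Fasl, which encodes a death ligand, fell from 19.4 ± 7.65 to 4.44 ± 1.04 CPM (-2.12, SE 0.42), and Tmem20, Dexi, Btbd2, Mxd3, Hras1, Slain1 and Oxsr1 fell with log2 fold changes between -2.41 and -2.06. All 141 genes had no overlap between the 3 WT and the 3 RBM3KO libraries. Selection by the test favours such genes, so this adds no support to the calls. Of the tested genes 18.9% were separated in this way, where chance gives 10%. At an unadjusted p under 0.05, 621 genes were higher and 781 lower. The count fell whichever library was left out, and a group of 2 samples gives the test less to work with. Without WT replicates 1, 2 and 3 in turn, 11, 52 and 66 genes were called. There were 77 without RBM3KO replicate 1, 40 without RBM3KO replicate 2 and 98 without RBM3KO replicate 3. DESeq2 called 433. The Cebpb value also moved, to -3.58 without WT replicate 3 and -5.94 without RBM3KO replicate 3, and Fam108c moved to -2.79 without WT replicate 3. The Cebpb call ended without each library in turn except RBM3KO replicate 3. It also ended with no filter, at 10 CPM or more in 3 libraries, with limma-voom, after the GC corrections and at equal depth. The calls of Il10 and Ctla4 ended without each library in turn except RBM3KO replicate 2. After the GC correction the calls of Nr1d2, Il10, Ctla4 and Wls ended, and after that for GC content and length those of Nr1d2, Ctla4 and Wls. Without each of the 6 libraries in turn, the calls of Gpr97, Nr1d2, Wls, Frmd4b, Mxd3 and Fasl ended. The replicate block ended the calls of Gpr97, Nr1d2, Il10 and Fasl, and limma-voom those of Gpr97, Fam108c, Cdk2ap1 and Fasl. The non-robust fit ended the calls of Wls and Frmd4b, and equal depth that of Frmd4b. Of the 35 genes past the threshold that the rule for named genes takes, 4 kept the call without WT replicate 1 (Ostf1, Fam108c, Ube2c and Ccna2). The number was 14 without WT replicate 2, 13 without WT replicate 3, 18 without RBM3KO replicate 1, 12 without RBM3KO replicate 2 and 22 without RBM3KO replicate 3.

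Cell cycle genes were lower in RBM3KO. Of the 26 genes of the list, all of them tested, 15 fell and 11 did not pass the test, and 22 were lower when adjusted over the list alone. The estimate was below 0 for all 26, with a median log2 fold change of -0.97. Ube2c, which encodes a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 152 ± 29.0 to 51.9 ± 6.51 CPM (log2 fold change -1.55, SE 0.17). Ccna2, encoding cyclin A2, fell from 128 ± 20.5 to 46.6 ± 4.18 CPM (-1.46, SE 0.16), Cdk1, the mitotic kinase, from 119 ± 8.54 to 47.9 ± 7.46 CPM (-1.31, SE 0.16), and Birc5, or survivin, from 138 ± 5.82 to 63.2 ± 10.5 CPM (-1.12, SE 0.15). Camera called the list lower (adjusted p = 5.2e-24), with an adjusted p = 0.0937 with an estimated correlation and a fry adjusted p = 0.0155. The members called lower numbered 2 without WT replicate 1, 9 without WT replicate 2, 9 without WT replicate 3, 8 without RBM3KO replicate 1 and 7 without RBM3KO replicate 2. In the same libraries the summed CPM (of the total count) of the B cell markers was 93.0 ± 15.1 in WT and 52.0 ± 6.89 in RBM3KO, and that of the macrophage, monocyte and dendritic cell markers 4330 ± 513 and 3111 ± 375. Malat1, a nuclear RNA named after its value was seen, stood at 256 ± 47.9 CPM in WT and 500.4 ± 208 CPM in RBM3KO, with no overlap (edgeR adjusted p = 0.109). The same libraries stand behind every list described here.

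**Figure D1:**
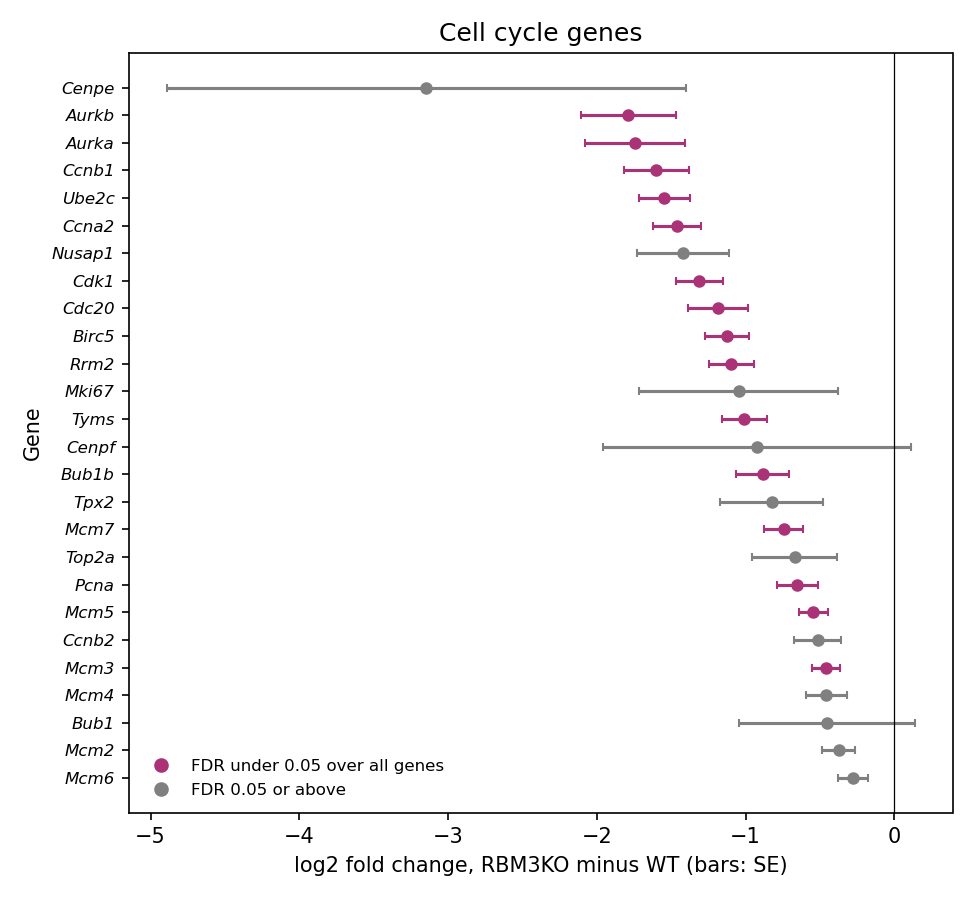
Log2 fold change, RBM3KO minus WT, of the 26 cell cycle genes, with bars for the standard error and colour for the edgeR test over all genes. All 26 points lie below 0, and 15 of them pass the threshold.

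Camera at the preset correlation called genes of type 2 immunity higher in RBM3KO as lists, with few single genes past the test. Fry called the type 2 effector list (fry adjusted p = 0.0323) and not the ILC2 identity list (fry adjusted p = 0.0575). Both lists hold Il5, Il13 and Areg, and Il10 also stands among the inhibitory receptors and regulators, so these lists are not independent. Of 15 tested type 2 effector genes, 1 rose (Il10) and 14 did not pass, with 6 higher when adjusted over the list alone and a median log2 fold change of 0.55 (camera adjusted p = 4.58e-06; adjusted p = 0.104 with an estimated correlation). Il5, the cytokine that drives eosinophils, stood at 627 ± 83.9 CPM in WT and 874 ± 49.9 CPM in RBM3KO (log2 fold change 0.48, SE 0.11, edgeR adjusted p = 0.0602). Il13, which drives mucus production, had 246 ± 29.0 and 359 ± 106 CPM (0.55, SE 0.18, edgeR adjusted p = 0.217). Il4 had a log2 fold change of 1.04 (edgeR adjusted p = 0.106), Areg, encoding the tissue-repair factor amphiregulin, 0.68 (0.146), Il9 2.39 (0.349) and Csf2 1.30 (0.349), and none of these passed. Of 20 tested ILC2 identity genes, 0 passed over all genes, while 10 were higher and 1 lower when adjusted over the list alone, with a median of 0.25 (camera adjusted p = 4.58e-06; adjusted p = 0.113 with an estimated correlation). At an unadjusted p under 0.05, 1402 of the 11382 tested genes passed. Arg1, encoding arginase 1, stood at 2197 ± 117 and 2922 ± 412 CPM and Id2, a regulator that all ILCs need, at 1700.0 ± 64.3 and 2067 ± 220 CPM, neither past the test. Gata3, the master regulator of ILC2s, had a log2 fold change of 0.12 (edgeR adjusted p = 0.830), Rora 0.61 (0.179), the IL-33 receptor gene Il1rl1 0.61 (0.138), Il7r 0.61 (0.0922) and Klrg1 0.18 (0.444). The lower gene was Gfi1, named after its value was seen (-1.40, SE 0.30).

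**Figure D2:**
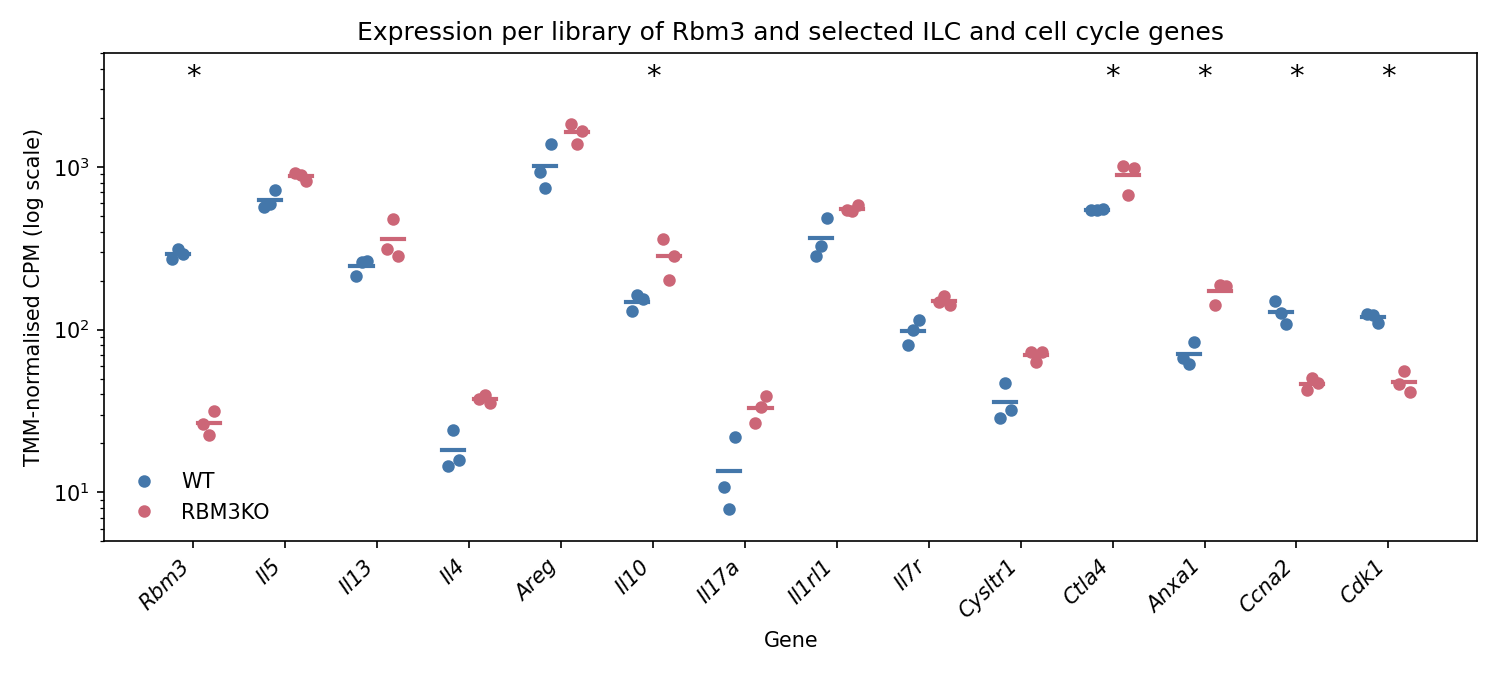
TMM-normalised CPM on a log scale of 14 genes in the 3 WT and 3 RBM3KO libraries, with points for libraries, lines for means and stars for genes with an edgeR adjusted p under 0.05. Rbm3 lies far lower in RBM3KO, and Il5 lies higher in all 3 RBM3KO libraries without a star.

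Of 15 tested ILC3 and type 17 genes 0 passed over all genes and 3 were higher when adjusted over the list alone, with a median log2 fold change of 0.34 (camera adjusted p = 0.000219; adjusted p = 0.0937 with an estimated correlation). Il17a, the type 17 cytokine, stood at 13.5 ± 7.38 and 33.1 ± 6.13 CPM (log2 fold change 1.28, SE 0.38, edgeR adjusted p = 0.168) and Il22 at 0.529 ± 0.677 and 4.39 ± 1.66 CPM (2.99, SE 1.34, edgeR adjusted p = 0.401). The lymphotoxin gene Ltb had 1222 ± 113 and 1361 ± 240 CPM, and Tmem176b 381 ± 29.3 and 480.1 ± 48.8 CPM. Of 20 tested ILC1, NK and cytotoxic genes 1 fell (Fasl) and 19 did not pass, with 1 higher and 1 lower when adjusted over the list alone and a median of -0.64 (camera adjusted p = 0.0364; adjusted p = 0.616 with an estimated correlation). That call ended without WT replicate 2, where the median was -0.26 (adjusted p = 0.436), and without RBM3KO replicate 3 (adjusted p = 0.0582). It also ended at 10 CPM or more in 3 libraries (median -0.57, adjusted p = 0.112), and fry did not call the list (adjusted p = 0.540). Tbx21, the regulator of ILC1s, had a log2 fold change of -0.67 (edgeR adjusted p = 0.595) and Ifng -0.39 (0.921).

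Camera at the preset correlation called activation genes and inhibitory receptors both higher as lists, and of these fry called the activation list alone. Of 21 tested activation and NF-kB genes, 2 rose and 19 did not pass, with 9 higher when adjusted over the list alone and a median log2 fold change of 0.31 (camera adjusted p = 1.03e-08; adjusted p = 0.0566 with an estimated correlation; fry adjusted p = 0.00281). Tnfaip3, the NF-kB inhibitor A20, rose from 1176 ± 166 to 1692 ± 146 CPM (0.53, SE 0.11), and Cd44, an adhesion receptor of activated lymphocytes, from 409 ± 45.2 to 582 ± 42.8 CPM (0.51, SE 0.11). Both calls ended with the non-robust fit and after the GC corrections. The Cd44 call also ended without each of the 6 libraries in turn, and the Tnfaip3 call without each but WT replicate 3. Of 15 tested inhibitory receptors and regulators, 2 rose (Ctla4 and Il10) and 13 did not pass, with 5 higher when adjusted over the list alone. The median of that list was 0.30 (camera adjusted p = 2.24e-05, adjusted p = 0.168 with an estimated correlation, fry adjusted p = 0.0954). Of 13 tested eicosanoid receptors and enzymes, 1 rose, the prostacyclin receptor gene Ptgir, from 150 ± 12.3 to 227 ± 25.6 CPM (0.60, SE 0.12), and 12 did not pass, with 3 higher when adjusted over the list alone and a median of 0.21 (camera adjusted p = 0.0241; adjusted p = 0.283 with an estimated correlation). The list's call ended without WT replicate 1 (median 0.11, adjusted p = 0.207) and without RBM3KO replicate 2 (adjusted p = 0.0614), and its median was 0.34 without WT replicate 3 and 0.42 without RBM3KO replicate 1. The Ptgir call ended with the non-robust fit and without each of the 6 libraries in turn. Cysltr1, the cysteinyl leukotriene receptor, stood at 36.1 ± 9.88 and 69.6 ± 5.75 CPM (0.95, SE 0.22, edgeR adjusted p = 0.0730). Of 23 tested immediate early and dissociation genes, 1 fell, the quiescence factor Klf2 (-1.29, SE 0.21), and 22 did not pass, while the list was called higher with a median of 0.29 (4 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.00257; adjusted p = 0.522 with an estimated correlation). Its median was 0.45 without WT replicate 3. The Klf2 call ended without each WT library in turn and without RBM3KO replicate 2.

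Of 19 tested chemokine receptor and homing genes, 2 fell, among them the lymph node homing receptor Ccr7 (from 110 ± 16.9 to 58.4 ± 10.3 CPM, log2 fold change -0.91, SE 0.18), and 17 did not pass. The median of that list was 0.19 and its mean -0.001, and camera, with the direction up, did not call it (adjusted p = 0.131; 2 higher and 2 lower when adjusted over the list alone). It was called without RBM3KO replicate 2 (camera adjusted p = 0.0139) and with the replicate block (camera adjusted p = 0.0474). The Ccr7 call ended without each of the 6 libraries in turn. Of 22 tested AU-rich element and cold-inducible RNA-binding proteins, 2 fell, the splicing factor gene Sfpq (-1.28, SE 0.25) and Hnrnpab (-1.10, SE 0.22), with 5 lower when adjusted over the list alone, a median of 0.16 and a mean of -0.08 (camera, direction down, adjusted p = 0.976). The Sfpq call ended without each library in turn except RBM3KO replicate 3. The Hnrnpab call ended without each WT library in turn, without RBM3KO replicate 2, with no filter, at 10 CPM or more in 3 libraries, after the GC corrections and at equal depth. Of 25 tested interferon response genes 0 passed over all genes or over the list alone, with a median of -0.47 (camera adjusted p = 0.976). Irf7 had 156 ± 104 and 99.1 ± 39.9 CPM. Without WT replicate 2 the interferon list was called higher (median 0.37, adjusted p = 0.0149), and without WT replicate 3 it was called lower (median -0.92, adjusted p = 3.79e-05).

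No member of the metabolic, stress and ribosomal lists passed the test over all genes. The ER stress list had a median log2 fold change of 0.05 and a mean of -0.06 over 16 tested genes (camera, direction up, adjusted p = 0.976), with Hspa5 at 592 ± 110 and 646 ± 40.2 CPM and Calr at 396 ± 41.0 and 371 ± 20.2 CPM. The glycolysis and hypoxia list had a median of -0.07 and a mean of 0.003 over 19 (camera, direction up, adjusted p = 0.976), with 1 higher and 2 lower when adjusted over the list alone. Ldha stood at 4266 ± 88.5 and 3841 ± 359 CPM and Pkm2 at 2559 ± 67.8 and 2537 ± 186 CPM. The nuclear oxidative phosphorylation list had a median of -0.06 over 79 genes (camera adjusted p = 0.0945), with Atp5b at 2221 ± 119 and 2193 ± 109 CPM and Cox4i1 at 1342 ± 71.9 and 1337 ± 92.0 CPM, and it was called lower without RBM3KO replicate 1 (adjusted p = 0.0233) and without RBM3KO replicate 3 (adjusted p = 0.0413). The cytosolic ribosomal protein list had a median of -0.01 over 82 genes (camera adjusted p = 0.207), with Rplp0 at 4063 ± 103 and 3947 ± 308 CPM and Rps2 at 3325 ± 259 and 3088 ± 329 CPM. That list was called lower without RBM3KO replicate 1 (adjusted p = 0.00940) and without RBM3KO replicate 3 (adjusted p = 0.000132), and higher without RBM3KO replicate 2 (adjusted p = 0.00561).

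**Figure D3:**
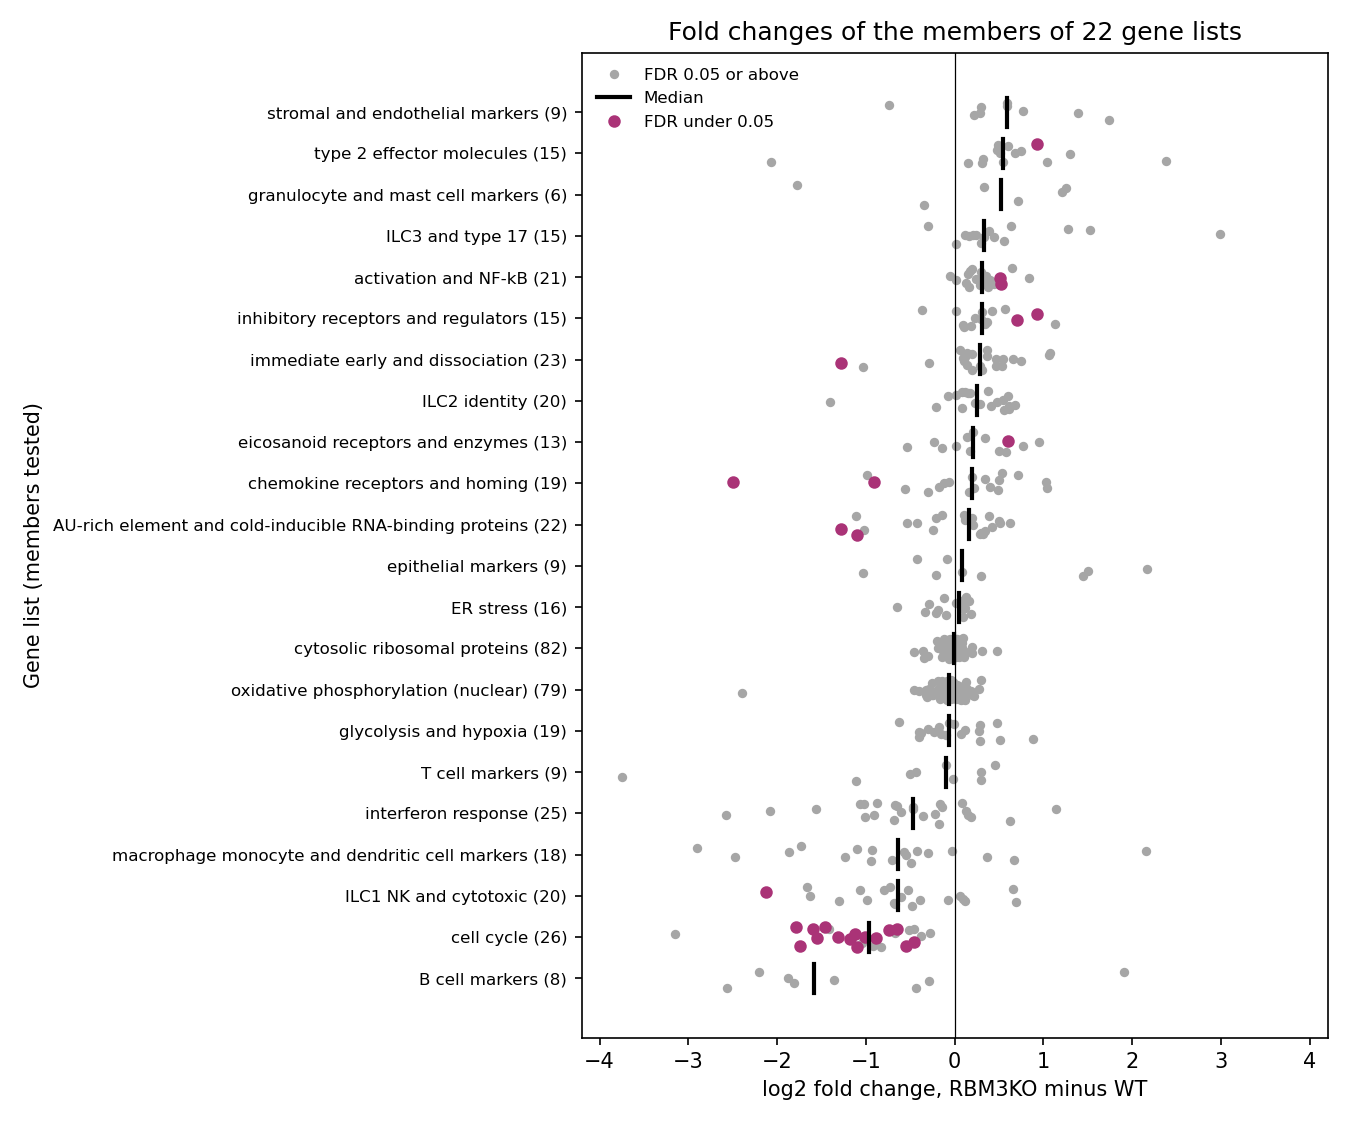
Log2 fold change, RBM3KO minus WT, of each tested member of the 22 tested gene lists, with black lines for medians and colour for members with an edgeR adjusted p under 0.05. The cell cycle list holds 15 of the coloured points and has its median at -0.97.

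Among the listed markers of other cell types, 0 members passed the test over all genes. Outside the lists, and named after their values were seen, Tyrobp, an adaptor gene of myeloid and NK cells, fell from 49.8 ± 7.84 to 19.5 ± 3.90 CPM (log2 fold change -1.34, SE 0.24), and Igj, the J chain gene of plasma cells, had 39, 25 and 103 counts in WT and 0 in each RBM3KO library (edgeR adjusted p = 0.109). The B cell markers had a median log2 fold change of -1.58 over 8 tested genes (1 lower when adjusted over the list alone; camera adjusted p = 0.0141; adjusted p = 0.193 with an estimated correlation; fry adjusted p = 0.0323). Cd79b stood at 45.6 ± 10.02 and 33.7 ± 5.34 CPM and Cd79a at 15.7 ± 2.65 and 4.46 ± 0.489 CPM (edgeR adjusted p = 0.0542). The call on the B cell markers ended without RBM3KO replicate 2 (adjusted p = 0.0614). The macrophage, monocyte and dendritic cell markers had a median of -0.64 over 18 genes (3 lower when adjusted over the list alone; camera adjusted p = 0.00441; adjusted p = 0.283 with an estimated correlation), with Cd74 at 1837 ± 418 and 1487 ± 170 CPM and H2-Ab1 at 904 ± 211 and 641 ± 73.1 CPM. Both genes belong to antigen presentation by MHC class II, which ILCs also use. That call ended without RBM3KO replicate 1 (median -0.44, adjusted p = 0.152), and the median was -0.42 without WT replicate 1, -0.43 without WT replicate 3 and -1.03 without RBM3KO replicate 2. The T cell markers were not called (16 listed, 12 with a row, 9 tested, median -0.10, camera direction up, adjusted p = 0.976). Lat stood at 273 ± 15.1 and 335 ± 11.2 CPM and Cd3g at 177 ± 28.4 and 243 ± 75.0 CPM. The T cell receptor genes Trac, Trbc1, Trbc2 and Trdc have no row, so this list does not bound carried-over T cells. The granulocyte and mast cell markers had 21 listed members, 13 with a row, among them Cpa3 (17.1 ± 4.55 and 13.5 ± 1.59 CPM) and Ccr3 (5.15 ± 1.78 and 6.42 ± 7.84 CPM). They were not called (6 tested, median 0.53, camera adjusted p = 0.976). The same held for the stromal and endothelial markers (9 tested, median 0.59, adjusted p = 0.273), with Pecam1 at 52.1 ± 9.84 and 60.3 ± 2.41 CPM and Eng at 29.0 ± 20.1 and 35.3 ± 18.4 CPM. The epithelial markers (9 tested, median 0.08, camera direction down, adjusted p = 0.576) were not called either, with Sftpc at 32.2 ± 37.9 and 88.5 ± 138 CPM and Sftpa1 at 11.2 ± 14.2 and 32.1 ± 49.3 CPM. With 1 library left out these 4 lists were not called either, but their medians moved. The epithelial median ran from -1.36 without RBM3KO replicate 3 to 0.95 without WT replicate 2, and the granulocyte and mast cell median from -0.15 without RBM3KO replicate 3 to 1.25 without RBM3KO replicate 1. The stromal and endothelial median ran from 0.22 without RBM3KO replicate 3 to 0.86 without RBM3KO replicate 2, and the T cell median from -0.29 without RBM3KO replicate 2 to 0.10 without RBM3KO replicate 1. Of the erythroid and platelet markers only Pf4 was tested (0.588 ± 0.394 and 0.587 ± 1.02 CPM), and the mitochondrially encoded genes have no row in the table used here.

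In all, camera called 11 of the 22 tested lists, 7 higher and 4 lower. With an estimated correlation 0 lists were called, and fry called 5: type 2 effector molecules, ILC3 and type 17, activation and NF-kB, cell cycle and B cell markers.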

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

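The corrections for GC content and for GC content and length, and the fit at equal depth, were chosen after seeing the data; the other alternatives were fixed before. All 141 changed genes kept their direction in every alternative on all 6 libraries that tested them (140 were tested at 10 CPM or more in 3 libraries), but the counts moved. As none of the 141 overlapped between the genotypes, leaving out 1 library could not turn their direction. DESeq2 called 433 genes (158 higher, 275 lower), which include all 141. Genes called higher numbered 59 with limma-voom sample weights, 48 with no filter on low counts and 59 at 10 CPM or more in 3 libraries, against 28 in the main test. Against a minimum fold change of 1.5, 6 genes were called, 0 higher and 6 lower, 2 of them in the cell cycle list; this test asks for more than a change, so a lower count follows from its construction. Leaving out 1 library gave 11 (without WT replicate 1) to 98 (without RBM3KO replicate 3) changed genes, 1 to 18 higher, 10 to 84 lower and 2 to 10 cell cycle members; a group of 2 samples gives the test less to work with. Of the 35 called genes that the rule for named genes takes, 4 kept their call without WT replicate 1 and 22 without RBM3KO replicate 3. RLE scaling called 136 genes, upper-quartile scaling 141, the non-robust fit 125, GC correction 129 (122 shared), GC and length correction 135 (121 shared) and equal depth 162 (135 shared). Of the 22 tested lists, 11 were called in the main test, 0 with an estimated correlation, 5 by fry and 10 to 12 with 1 library left out. The interferon list, not called in the main test, had medians from -0.927 to 0.374 and was called higher without WT replicate 2 (0.374) and lower without WT replicate 3, and the ribosomal protein list had medians from -0.094 to 0.077 and was called higher without RBM3KO replicate 2 (0.077) and lower without RBM3KO replicates 1 or 3 in turn; the cause was not tested. Over named genes and lists, 35 of 1450 gene values and 25 of 304 list values changed sign with neither value past the threshold, and these are not counted as reversals. The deviations of same-numbered libraries from their genotype mean correlated at 0.056, 0.057 and 0.005 over genes. All lay under the cut of 0.1 used here, so the numbers were not taken to pair samples. Yet 4 of 6 libraries correlated best with their own number, so a batch shared by number is not excluded. With the replicate block, 148 genes were called (113 shared with the main test), the chemokine receptor list passed (adjusted p = 0.0474), and 4 named genes lost and 1 gained the call. In simulated counts with these library sizes and 3 libraries per genotype, 36% of 2-fold changes were recovered. There were 9 false calls beside those 72 recovered genes.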

Other observations

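Of the tests below, those of the gene families, the other splits of the samples, the CPM lost by B cell and myeloid markers and the window around Rbm3 were chosen only after the results were seen, and the GC correction and equal depth were alternatives added after seeing the data. Families were grouped by symbol, 9 in all, and no enrichment was tested. Of 11 tested alpha and beta tubulins, 5 fell in RBM3KO (Tuba1b, Tuba1c, Tuba4a, Tubb4b and Tubb5) and 6 did not pass, with all 11 estimates below 0 and Tubb5 going from 2060 ± 149 to 1363 ± 110 CPM. Of 49 histone genes 5 fell, of 28 Cdc and Cdca genes 4 fell, of 25 kinesins 1 fell (Kif22) and of 18 centromere proteins 0 fell, with medians of -0.43, -0.36, -0.36 and -0.81. All 8 MCM helicase genes had estimates below 0 and 3 fell (Mcm3, Mcm5 and Mcm7; 2 with upper-quartile scaling); 6 of the 8 also stand in the cell cycle list. Of 8 genes of serine and one-carbon synthesis 2 fell, Phgdh, the first enzyme of serine synthesis (from 375 ± 29.7 to 218 ± 14.4 CPM), and Shmt1, with all 8 estimates below 0. Of 18 cytokine receptor subunits 1 rose, the common gamma chain Il2rg (from 2079 ± 47.6 to 2736 ± 203 CPM), and 17 estimates were above 0. Of 14 circadian clock genes 1 rose (Nr1d2), with 8 estimates above 0 and 6 below. These counts of signs were the same with RLE and upper-quartile scaling. Tubulin and histone copies share sequence, so single values there are uncertain.

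Single libraries stood apart within their genotype, in CPM of the total count. The summed CPM of the interferon list was 1932 in WT replicate 2 against 835 and 601 in the other WT libraries, and 1216 in RBM3KO replicate 2 against 688 and 848. The cytotoxic list summed to 1099 CPM in WT replicate 2 against 659 and 558. Sftpc, a transcript of alveolar type 2 cells, was at 246 CPM in RBM3KO replicate 3 and 76.9 CPM in WT replicate 2, and between 6.86 and 14.2 CPM in the other 4 libraries. Xist, a check of sex, which the labels do not give, was detected in all 6 libraries, at 27.8 to 67.1 CPM. The Y-linked genes planned beside it, Ddx3y, Eif2s3y, Kdm5d and Uty, have no row in the table, so the check rests on Xist alone. Malat1, a nuclear RNA, was at 264, 210 and 308 CPM in WT and at 429, 323 and 724 CPM in RBM3KO.

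With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. Each of the 9 splits other than the real one sets 2 libraries of 1 genotype with 1 of the other. Part of any genotype difference then stays between the groups, and the rest adds to the spread within them. These splits thus do not show what the tests give without a genotype difference. The real split gave 141 changed genes and was the only 1 of the 10 to give as many, with 0 the highest of the others. For the cell cycle list 1 of the 10 splits, the real one, gave a camera p as small (2.36e-25, with 2.01e-06 the smallest of the others). For the number of lists called by camera at the preset correlation, 2 of the 10 splits gave as many, 11 for the real one and 11 for the split of WT replicates 1 and 2 with RBM3KO replicate 2 against the rest. All of the 9 other splits gave the cell cycle list a camera p under 0.05, and fry called 5 lists in the real split and 0 in each of the others. Of the other called lists, camera gave a p as small in 4 of the 10 splits for the immediate early list (0.000818 in the real one, 1.73e-10 the smallest of the others) and for the cytotoxic list (0.0182 and 0.000344). It did so in 3 for the myeloid markers (0.0016 and 3.95e-05) and in 2 for the inhibitory receptors (5.1e-06 and 2.05e-07). For the 6 others it did so in the real split alone.

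Cell cycle genes were lower in RBM3KO, with a mean difference per library of -1.06 (SE 0.12, log2). GC content is argued against as the whole cause, since the difference was -1.07 (SE 0.12) after the GC correction. That correction had little to move, as the list's median GC content (47.8%) lay near that of the tested genes (50.6%). WT replicate 1 held fewer counts than RBM3KO replicates 1 and 2 and yet had a higher mean of the list. At equal depth the difference was -0.98 (SE 0.12). Thinning keeps the expected CPM of a gene, so that value does not decide whether depth contributes to the fall. Fewer carried-over cells of another type in RBM3KO may account for part of it and stay open: B cell markers had a median of -1.583, below that of the cycle list, and lost 2.13% as many CPM (41.0, SE 9.57) as the cycle genes did (1926, SE 277), but 5 of the listed markers, among them the immunoglobulin genes Ighm and Igkc, have no row in the table, so that sum does not bound the B cells. The myeloid markers lost 1220 CPM (SE 367), 63.3% as many, with a median of -0.64 (SE 0.21); 4 MHC class II genes, which ILCs also express, made up 82.9% of that loss, and neither type should pass a Lin- gate. The genotype itself stays among the open explanations, and no test here decides between it and a change in which cells were sorted.

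Some genes were at 0 in all libraries of 1 genotype and at 10 or more counts in each of the other, 5 at 0 in WT and 19 at 0 in RBM3KO. The rule takes raw counts, and totals ran from 7498247 in RBM3KO replicate 3 to 25068137 in WT replicate 3. A shallower library reaches 0 more easily and 10 counts less easily, so 5 and 19 are not a fair comparison of the genotypes. BC147527 (chromosome 13, 120300392 to 120308779) had 176, 414 and 570 counts in WT and was at least 282-fold lower in RBM3KO, and Rpgr (chromosome X, 10073621 to 10216920) was at least 99.5-fold higher in RBM3KO, against a floor of 3 counts over the group. Of the 10 splits 2 gave as many such genes (24 in the real one, 32 in the highest other, which sets WT replicates 1 and 2 with RBM3KO replicate 2), too few for a share under 0.05. Rpgr and Suv39h1 (start 8061171; log2 fold change -0.85, adjusted p = 0.0393), which was not at 0, were the 2 called genes within 10 Mb of Rbm3, so DNA of another strain around the targeted locus may contribute. In that window 20.5% of 44 tested genes had an unadjusted p under 0.05 against 12.3% elsewhere (odds ratio 1.84, 95% interval 0.775 to 3.91, Fisher's exact p = 0.106), which leaves this open; the test does not cover BC147527 or 3110070M22Rik, which also lies on chromosome 13 (start 119487261) and had 36, 19 and 31 counts in WT and 0 in each RBM3KO library (adjusted p = 0.186), and DNA of another strain there was not tested.

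Genes called lower had a higher transcript GC content (median 53.5%) than the tested genes (50.6%) or the cell cycle list (47.8%). The slope of log2 CPM on GC content overlapped between the genotypes (the lowest WT slope lay -0.076 per 10 percentage points from the highest RBM3KO slope), which is consistent with a GC bias of single libraries unrelated to genotype. After the GC correction 103 genes were lower, 100 of them shared, at a median GC content of 52.2%, and the lower genes outside the cell cycle list went from a median log2 fold change of -1.19 to -1.18, so this bias is argued against as the whole cause of their fall.

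A hypothesis from the known binding of RBM3 to AU-rich sequence was that transcripts with an AU-rich nonamer in the 3' untranslated region shift in RBM3KO. Of 10777 searched genes 3597 had at least 1 nonamer. Their mean log2 fold change exceeded that of the rest by 0.052, and by 0.025 after the GC correction, with a camera p of 0.283 and 0.605. With a standard error between libraries of 0.034 after the correction, a shift of 0.05 is not excluded, and the question stays open.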
